A study of Homo sapiens with 18 samples.

How the data were processed

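ChIP-seq of TLE3 and FOXA1 was analysed from peak lists of 12 libraries, 2 replicates per factor in MDA-MB-453, SKBR3 and T47D. The 6 further samples of the series are inputs, for which no file was used here. Per the labels' protocols, cells were fixed and immunoprecipitated with a kit for transcription factors, TLE3 cells were treated with an additional crosslinker before formaldehyde, and libraries were made from chromatin and input DNA with a low-input amplification kit. Per the labels, the antibodies were from Diagenode for FOXA1 and Proteintech for TLE3. Per the submitters' processing notes, Trim Galore, BWA 0.7.5a, SAMtools and MACS2 were used on hg38. The settings of the caller, the control used for each list and any filter are not given in the sources used here. Each of the 12 immunoprecipitated libraries has its own deposited list, so peaks were not pooled over replicates.

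Each deposited list has 5 columns, with chromosome, start, end, a name and a peak score. The score is the authors' own value per peak. Its lowest value lay between 2.00 and 2.04 in the 12 lists, and the sources used here do not name the quantity. It was used only to rank or filter peaks within a list. The lists give no summits, so the centre of a peak stands for its position. They give no read counts, so depth is unknown and differences in peak number can come from depth as well as binding. Of 1134209 peaks, 15 lay outside chromosomes 1 to 22 and X and were left out. No pair of the 66 pairs of lists shared more than 0.00881% identical intervals, so no library was taken for a copy of another.

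Samples were grouped by the line and factor in their titles. A site is a merged region holding a peak of both replicates of a group. Overlap means at least 1 bp. Gene positions came from a RefSeq gene table of GRCh38.p14, the same build, with 59098 annotated genes, of which 19974 are protein-coding. The table gives no strand, so the planned distance to a transcription start was replaced by the distance to either end of the gene, within 1 kb for peaks near gene ends and 50 kb for genes near a site. All 228 entries of the 13 gene lists matched a symbol. The lists cover luminal identity, basal identity, epithelial-mesenchymal transition and TGF-beta, WNT and TCF genes, NOTCH and HES genes, estrogen response, androgen response, ERBB pathway, corepressors, RUNX with GRHL, AP-2, forkhead and GATA factors, cell cycle, housekeeping and genes of other cell types. Results on the forkhead motif need a genome sequence and were not run.

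The number of peaks and the percent near gene ends were compared between factors by exact two-sided permutation of factor labels within lines, over 216 arrangements. Values per library were tested by exact two-sided sign-flip permutation, over 64 arrangements for 6 libraries and 32 for 5. Overlap was compared with 1000 random placements on the same chromosome (100 for the alternatives), one-sided. Peak strength is the probability that a peak overlapping a site of the other factor has a higher score than another peak of its list. List genes were compared with the other protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment over 78 tests (13 lists, 3 lines, 2 factors) and with 10000 random lists, matched for TLE3 on the number of FOXA1 sites within 50 kb and for FOXA1 on gene length. The threshold was 0.05. Genes are neighbours and not independent replicates. The best ranked 3 members of each list were named, by the mean percentile of their best TLE3 site over the lines, with up to 3 members lacking a site in each line, the genes nearest to the 5 highest ranked sites of each kind, and FOXA1, TLE3, ESR1, ERBB2, GATA3, KRT5, KRT8 and TGFB2 whatever their values. Only some of the names this rule gives are printed, and results for some genes are not reported here.

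Also run, as fixed before the data were seen, were the upper 50% of each list by score, equally long lists of 21149 peaks, each library left out in turn, all contigs, an overlap of 50% of the shorter interval, centres within 250 bp, sites from either replicate, leaving out the densest 1% of 1 Mb bins, a 3 kb window, ends of protein-coding genes alone, peaks outside gene ends, peaks of similar width, 10 kb and 100 kb to genes, the nearest gene alone, and a replicate block. Added after seeing the data were a score of 10 or more, random shifts by 10 to 100 kb, the gene body with 50 kb on each side, and random lists matched on gene length. The choice to set values without the library labelled SKBR3 TLE3 replicate 2 beside the main ones also came after, although leaving out each library was planned. The scripts were tested on simulated data. Planted overlaps of simulated TLE3 peaks with T47D FOXA1 peaks of 20.8%, 51.1% and 80.7% came back as planted, Fisher's exact test called 3.5% of 200 random lists of 20 genes near T47D TLE3 peaks and 100% of planted ones, matched lists called 1.5%, and the permutation within lines gave p under 0.05 in 4.4% of 500 simulations with no difference. The other simulated peaks were kept only where they missed FOXA1, so the recovered overlap checks the counting alone. Planted lists held only genes with a site, so their calls do not measure power for weaker lists. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.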

Results

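Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map TLE3, a Groucho family corepressor that binds DNA through partner transcription factors, and FOXA1, a forkhead pioneer factor of luminal breast cells. The cells were 3 established luminal breast cancer lines. MDA-MB-453 is an estrogen receptor negative line, SKBR3 is an ERBB2-amplified line, and T47D is an estrogen receptor positive line. Each factor was mapped in 2 replicates per line, which the labels call biological, and this gave 12 libraries with a peak list each. The labels do not say how the replicates were grown, so p-values of the tests over libraries measure the spread between these libraries. Random placement takes sites as units, and Fisher's exact test and matched random lists take genes, so their p-values hold no spread between libraries. The 12 lists held 1134209 peaks. FOXA1 lists held 107598 to 188029 peaks on chromosomes 1 to 22 and X, and TLE3 lists held 21149 to 94363. Read counts are not part of the lists, so the sequencing depth of each library is unknown.

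FOXA1 peaks were largely shared between replicates. In MDA-MB-453, 72.7% and 90.2% of the peaks of FOXA1 replicates 1 and 2 were overlapped by the other replicate, in SKBR3 85.3% and 78.5%, and in T47D 77.4% and 76.8%. For TLE3, the shorter list was held almost whole in the longer list in MDA-MB-453 (97.0%) and T47D (96.8%), while 51.0% and 46.3% of the longer lists were overlapped. In SKBR3, 33.9% of the 21149 peaks of TLE3 replicate 1 and 7.54% of the 94363 peaks of the library labelled SKBR3 TLE3 replicate 2 were overlapped by the other. Averaged over the 12 libraries the overlap was 67.8%, and without the library labelled SKBR3 TLE3 replicate 2 it was 77.2%. Among the 20000 highest scored peaks of each list, replicates of one group shared 83.2% to 92.8%, while 2.10% to 6.51% of the top peaks of the library labelled SKBR3 TLE3 replicate 2 overlapped those of any other list. The main results below are therefore also given without that library. A site is a merged region that holds a peak of both replicates of a group, and a site of SKBR3 without that library is a peak of replicate 1.

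**Figure D1:**
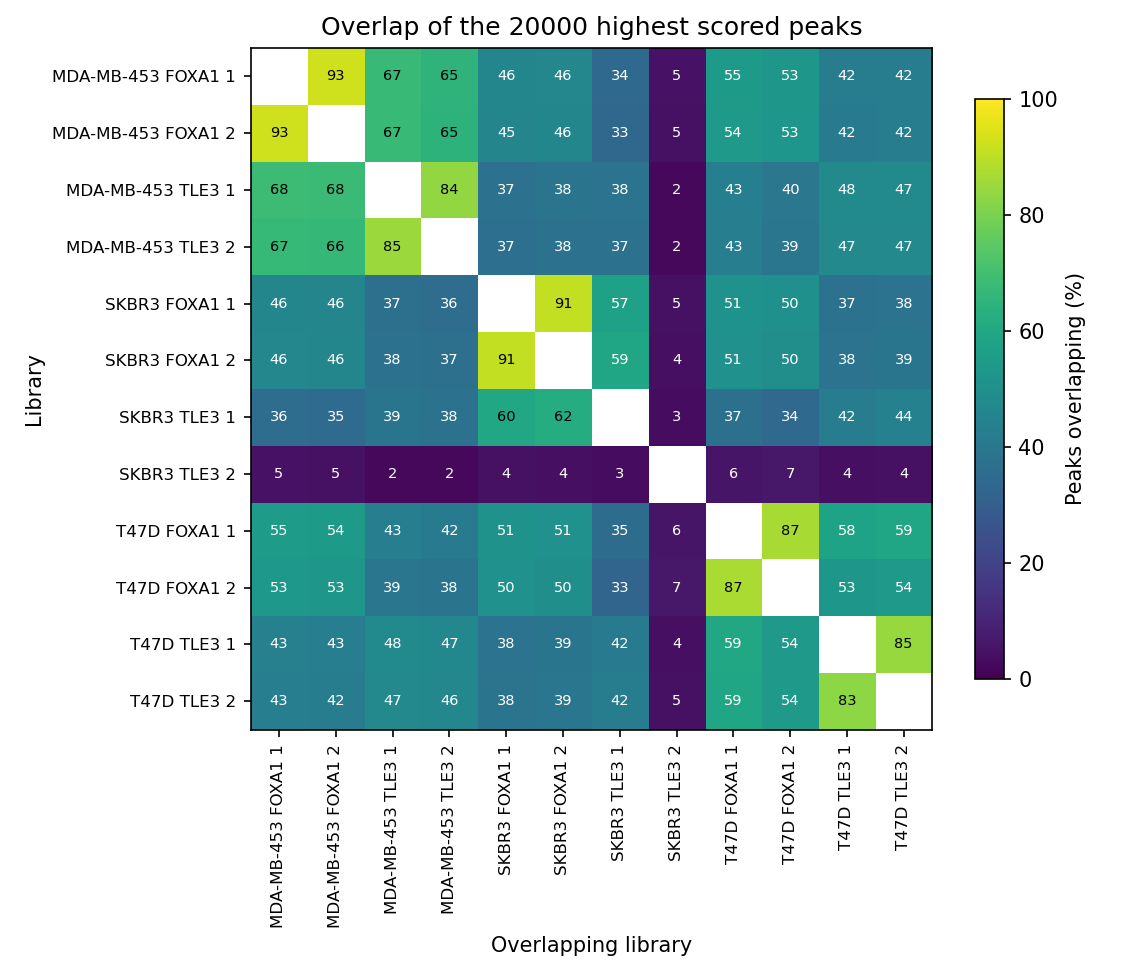
Percent of the 20000 highest scored peaks of each library (vertical axis) that overlapped the 20000 highest scored peaks of another library (horizontal axis), with the colour scale in percent. The library labelled SKBR3 TLE3 replicate 2 stands apart, with 2.10% to 6.51% of its top peaks shared with another list.

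FOXA1 had more peaks than TLE3 in each of the 3 lines. In MDA-MB-453 there were 170526 ± 24752 FOXA1 peaks and 32702 ± 14137 TLE3 peaks (SD, n = 2 each), and in T47D 148149 ± 1225 and 45781 ± 22077 (SD, n = 2 each). SKBR3 had 112183 ± 6484 FOXA1 peaks and 57756 ± 51770 TLE3 peaks (SD, n = 2 each), the latter from 21149 and 94363. The geometric mean number of peaks was 3.61-fold higher for FOXA1, a log2 difference of TLE3 from FOXA1 of −1.85. An exact two-sided permutation of the factor labels within lines gave p = 0.00926, the smallest that its 216 arrangements can give, and the log2 difference was −2.21 without the library labelled SKBR3 TLE3 replicate 2 (exact permutation p = 0.00926). Cells for TLE3 were crosslinked with an additional reagent and the antibodies differ, so the numbers of peaks compare immunoprecipitations, not amounts of bound protein.

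**Figure D2:**
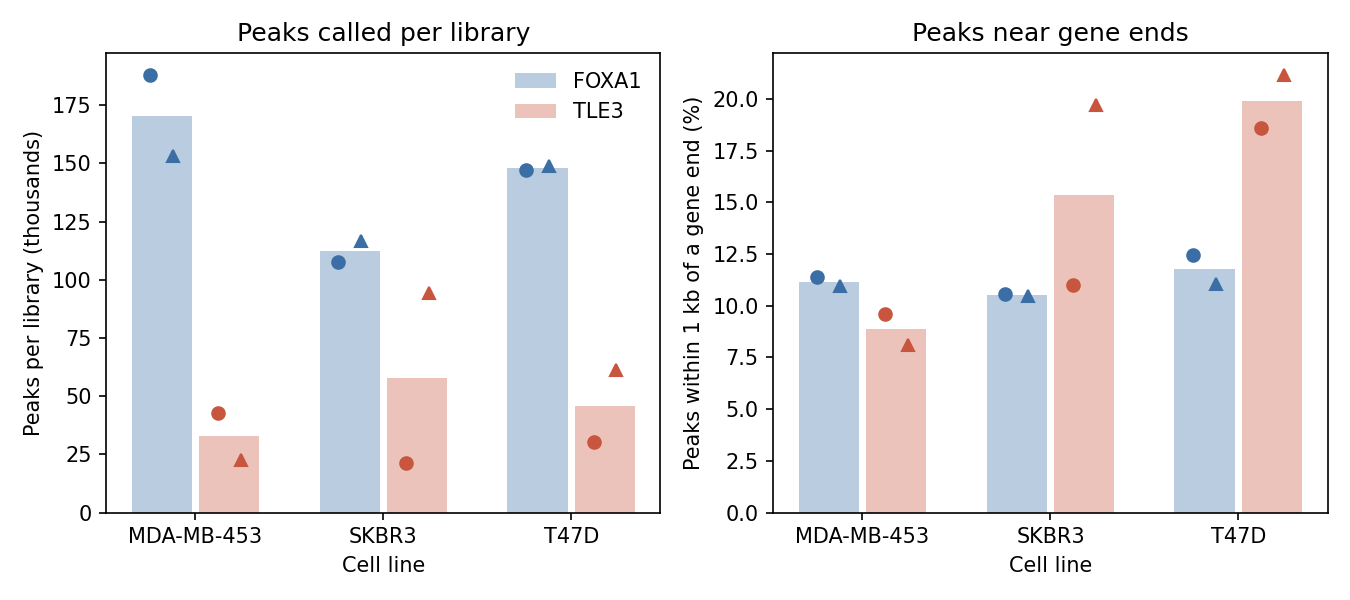
Number of peaks per library (left, axis in units of 1000 peaks) and percent of peaks with their centre within 1 kb of a gene end (right), by cell line, with FOXA1 in blue and TLE3 in red. Bars are means of 2 libraries, circles are replicate 1 and triangles replicate 2, and each FOXA1 library had more peaks than each TLE3 library.

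Most TLE3 sites overlapped FOXA1 sites. In MDA-MB-453, 21622 of 21768 TLE3 sites (99.3%) overlapped a FOXA1 site by at least 1 bp, in SKBR3 6361 of 6976 (91.2%) and in T47D 24661 of 28354 (87.0%). Without the library labelled SKBR3 TLE3 replicate 2 the SKBR3 value was 19764 of 21149 (93.5%). The TLE3 site with the highest rank by the authors' own peak score in T47D lay in TMEM150C (chromosome 4, 82552785 to 82553878, hg38, 8922 bp from a gene end), and a site inside the potassium channel gene KCNH5 (chromosome 14, 62800199 to 62801196 in MDA-MB-453) was among the 5 highest in both MDA-MB-453 and T47D. Both overlapped FOXA1 sites, as did the high ranked sites in MITF, which encodes a melanocyte lineage transcription factor (chromosome 3, 69832779 to 69834390), and near DUSP4, a phosphatase of MAP kinases (chromosome 8, 29326849 to 29328304), in MDA-MB-453. TLE3 sites placed at random on their chromosomes overlapped FOXA1 sites for 5.37%, 4.54% and 4.70% in the same order of lines (3.06% for SKBR3 replicate 1 alone). With TLE3 sites shifted by only 10 to 100 kb, random overlap was higher, at 7.51%, 9.24% and 7.42%. Against placement on the whole chromosome the observed overlap was 18.5, 20.1 and 18.5 times as large (30.5 for SKBR3 replicate 1 alone), and the one-sided permutation p = 0.000999 in each line is the smallest that 1000 placements can give.

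The overlap of single TLE3 libraries with the FOXA1 sites of their line was 97.6% ± 1.24 in MDA-MB-453 and 78.1% ± 9.73 in T47D (SD, n = 2 each). In SKBR3 it was 93.5% for replicate 1 and 21.7% for the library labelled replicate 2. SKBR3 sites taken from that library alone, without SKBR3 TLE3 replicate 1, thus overlapped FOXA1 for 21.7%, against 4.25% for random placement. That library stands apart from the other lists, so overlap above random placement does not by itself show binding particular to TLE3. With equally long lists the overlap of sites was 71.1% in MDA-MB-453, 46.0% in SKBR3 and 58.5% in T47D, and with sites taken from either replicate it was 36.3% in SKBR3.

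In the other direction, TLE3 was found at a minority of FOXA1 sites with the lists at their full lengths. It was found at 21364 of 135315 FOXA1 sites in MDA-MB-453 (15.8%), 6529 of 90520 in SKBR3 (7.21%) and 24663 of 112670 in T47D (21.9%), and in SKBR3 at 18937 (20.9%) without the library labelled TLE3 replicate 2. Random placement gave 0.876%, 0.364% and 1.21%, and shifts by 10 to 100 kb gave 1.23%, 0.745% and 1.90% (placement permutation p = 0.000999 in each line, the smallest possible, one-sided). In MDA-MB-453 it was 29.7% without TLE3 replicate 2 and 16.1% without TLE3 replicate 1, in SKBR3 22.4% without TLE3 replicate 1, and in T47D 37.8% without TLE3 replicate 1 and 22% without TLE3 replicate 2. With sites taken from either replicate it was 20.6%, 29.6% and 27.8%. With equally long lists it was 63.4%, 1.80% and 55.3%, so TLE3 was not at a minority of FOXA1 sites in MDA-MB-453 and T47D at equal length. At equal length a SKBR3 TLE3 site still needs a peak of the library labelled replicate 2. Of that library's 20000 highest scored peaks, 3.20% overlapped those of replicate 1.

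**Figure D3:**
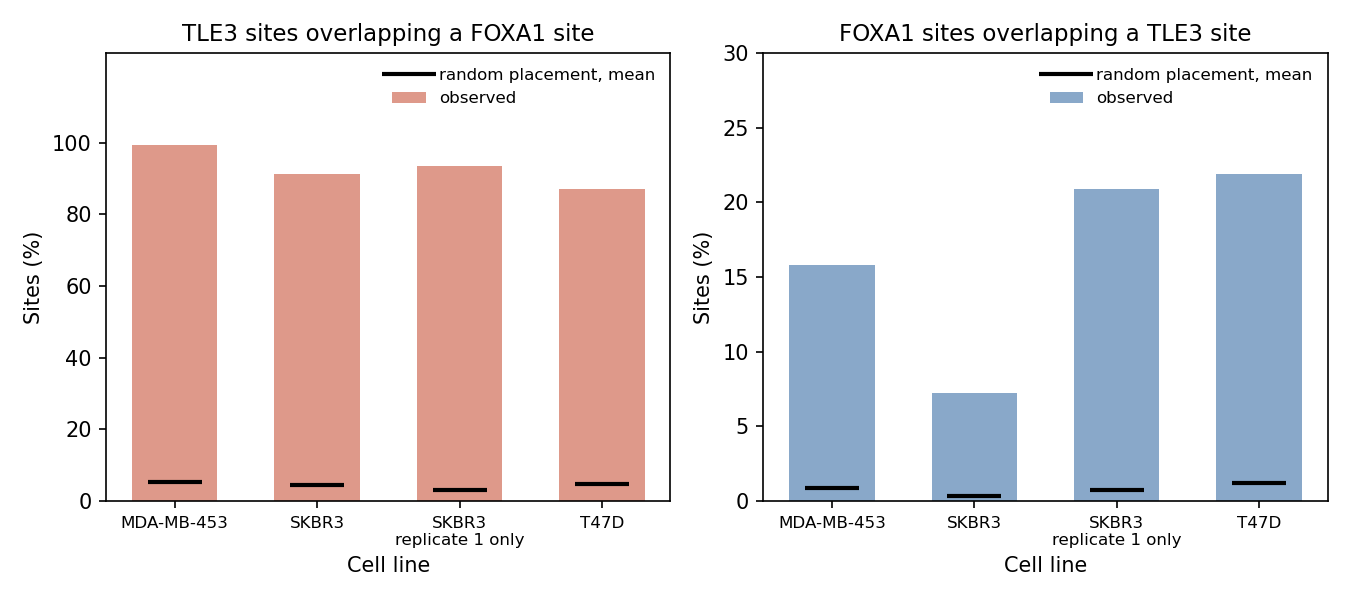
Percent of TLE3 sites that overlapped a FOXA1 site (left) and of FOXA1 sites that overlapped a TLE3 site (right), by cell line, with SKBR3 also shown for TLE3 replicate 1 alone. Bars are observed percentages and black lines the mean of 1000 random placements, such as 99.3% against 5.37% for TLE3 sites in MDA-MB-453.

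TLE3 peaks followed the FOXA1 sites of their own line more than those of the other lines in 5 of the 6 libraries. In MDA-MB-453, 96.7% and 98.5% of TLE3 peaks overlapped FOXA1 sites of MDA-MB-453, against means of 62.5% and 71.0% for the FOXA1 sites of SKBR3 and T47D. SKBR3 TLE3 replicate 1 had 93.5% against 69.7%, and the T47D libraries had 85.0% and 71.2% against 70.8% and 59.3%. Those T47D means join 77.3% and 66.1% for the FOXA1 sites of MDA-MB-453 with 64.3% and 52.55% for those of SKBR3. MDA-MB-453 had the most FOXA1 sites (135315) and SKBR3 the fewest (90520), for which this comparison does not adjust. The library labelled SKBR3 TLE3 replicate 2 went the other way, with 21.7% against 26.7%. The mean difference was 17.8 percentage points, and an exact two-sided sign-flip permutation over 6 libraries gave p = 0.0625, where 0.0313 is the smallest it can give. Without that library it was 22.3 points and positive in 5 of 5 libraries, with an exact permutation p = 0.0625 that is the smallest 5 libraries allow. The 2 libraries of a line share their FOXA1 sites and are not independent of each other.

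TLE3 peaks that did not overlap FOXA1 lay near gene ends more often than those that did. Here a peak near a gene end has its centre within 1 kb of either end of an annotated gene. In T47D such sites without FOXA1 included 1 in MYRIP, which encodes a linker of RAB27A to myosin (chromosome 3, 39808869 to 39810218, 630 bp from a gene end), and 1 next to the mitophagy receptor gene BNIP3 (chromosome 10, 131981421 to 131982431, 2 bp from a gene end). Both genes also had a site without FOXA1 among the 5 highest ranked of SKBR3 TLE3 replicate 1, at 538 bp and 112 bp from a gene end. The other 3 of the 5 highest ranked sites without FOXA1 in T47D lay 2266 to 58054 bp from the nearest end of a protein-coding gene. None of the 5 in MDA-MB-453 or of the 5 in SKBR3 with all libraries lay within 1 kb of such an end. Ends of other annotated genes, which count in the percentages below, were not measured for these single sites. Over the 6 TLE3 libraries, 13.3% ± 5.48 of peaks with FOXA1 and 29.8% ± 6.26 of peaks without it were near a gene end (SD, n = 6), and without the library labelled SKBR3 TLE3 replicate 2 11.7% ± 4.27 and 31.9% ± 3.93 (SD, n = 5). The difference of −16.5 percentage points was negative in 5 of 6 libraries and missed the threshold (exact two-sided sign-flip permutation p = 0.0625). It was 2.11 in that library and −20.2 without it (exact permutation p = 0.0625, the smallest for 5 libraries), and with equally long lists −5.0.

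Taken over all peaks, no difference between the factors in closeness to gene ends passed the test. TLE3 peaks were near a gene end for 14.7% ± 5.75 and FOXA1 peaks for 11.2% ± 0.722 (SD, n = 6 each), a difference of 3.54 percentage points with an exact permutation p = 0.148. It was 2.09 without the library labelled SKBR3 TLE3 replicate 2 (exact permutation p = 0.287), with TLE3 at 13.7% ± 5.81 (SD, n = 5), and 1.29 among the upper 50% of each list by score. By line, TLE3 peaks near gene ends made up 8.86% ± 1.06 in MDA-MB-453, 15.3% ± 6.17 in SKBR3 and 19.9% ± 1.80 in T47D (SD, n = 2 each).

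FOXA1 peaks at TLE3 sites carried higher scores than other FOXA1 peaks of the same list. The FOXA1 sites in DOP1B in SKBR3 (chromosome 21, 36187734 to 36188747) and DNPEP, an aspartyl aminopeptidase gene, in T47D (chromosome 2, 219398513 to 219399640) were among the 5 highest ranked of their line, and both overlapped TLE3 sites. All 5 of the highest ranked FOXA1 sites in MDA-MB-453 and all 5 in T47D overlapped a TLE3 site, against 3 of 5 in SKBR3. The SKBR3 count uses TLE3 sites that need a peak of the library labelled replicate 2. No such count was made for replicate 1 alone. A FOXA1 peak at a TLE3 site outranked one elsewhere with a probability of 0.853 ± 0.0645 (SD, n = 6), from 0.794 to 0.941 per library, where 0.5 is no difference. The exact two-sided sign-flip permutation p = 0.0313 is the smallest that 6 libraries can give, and 5 libraries cannot go below 0.0625, so leaving out any FOXA1 library ends the call (0.835 without MDA-MB-453 FOXA1 replicate 1, 0.838 without MDA-MB-453 FOXA1 replicate 2, 0.865 and 0.863 without SKBR3 FOXA1 replicates 1 and 2, 0.857 and 0.860 without T47D FOXA1 replicates 1 and 2). The probability was 0.877 without the library labelled SKBR3 TLE3 replicate 2 and 0.585 among peaks of similar width. The 2 FOXA1 libraries of a line were scored against the same TLE3 sites, so the 6 values are not independent, which the test does not account for.

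The reverse comparison did not pass. A TLE3 peak at a FOXA1 site outranked one elsewhere with a probability of 0.729 ± 0.140 (SD, n = 6; exact permutation p = 0.0625), above 0.5 in 5 of 6 libraries and 0.470 in the library labelled SKBR3 TLE3 replicate 2. Without it the probability was 0.781 (exact permutation p = 0.0625, the smallest for 5 libraries).

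TLE3 sites were mostly found in some lines and not others. Of 40916 merged TLE3 sites 2259 (5.52%) were found in all 3 lines, and 6365 of 47304 (13.5%) without the library labelled SKBR3 TLE3 replicate 2. FOXA1 sites were found in all 3 lines for 43624 of 196570 (22.2%). Of the 2259 shared TLE3 sites, 2147 (95.0%) also held FOXA1 in all 3 lines, and 6151 of 6365 (96.6%) without that library. The genes nearest to the highest ranked of these were AQP7, an aquaglyceroporin gene (chromosome 9, 33415444 to 33416062, 13184 bp from a gene end), PYURF (chromosome 4, 88514666 to 88515542) and CCDC190 (chromosome 1, 162846744 to 162847496). Without that library they were MALSU1, a mitochondrial ribosome assembly gene (chromosome 7, 23334414 to 23335360, within IGF2BP3), HMCN1 (chromosome 1, 185696425 to 185697540) and NEBL (chromosome 10, 20622535 to 20623476). The numbers of shared sites depend on the lengths of the lists, and differences between lines were not tested.

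Luminal identity genes, a list fixed with 12 others before the data were examined, were the list called near TLE3 in each of the 3 lines. A TLE3 site lay within 50 kb of either gene end for 20 of 22 luminal genes in MDA-MB-453, 17 of 22 in SKBR3 (21 of 22 for replicate 1 alone) and 22 of 22 in T47D. All 3 passed Fisher's exact test against the other protein-coding genes, of which 53.4%, 33.8% and 73.4% had such a site (55.6% for SKBR3 replicate 1 alone) (Benjamini-Hochberg adjusted p = 0.0108, 0.00301 and 0.0472 over 78 tests, and 0.00412 for SKBR3 replicate 1 alone). The best ranked members were ELF3, an epithelial ETS factor, with a TLE3 site 1665 bp from a gene end in MDA-MB-453 (chromosome 1, 202018294 to 202019404), KRT7, a simple epithelial keratin, and SPDEF, a luminal ETS factor with a site in T47D 61 bp from a gene end (chromosome 6, 34555724 to 34556813). Each member had a TLE3 site in at least 1 line. Random lists matched on the number of FOXA1 sites within 50 kb held on average 18.8, 15.0 and 21.6 genes with a TLE3 site, and the excess of the luminal genes over them did not pass the test (one-sided permutation p = 0.353, 0.229 and 0.681, and 0.229 for SKBR3 replicate 1 alone).

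The luminal and estrogen response lists gave the 4 calls among 39 tests of TLE3 sites, of which 8 had an unadjusted p under 0.05, and again 4, with 7 unadjusted, without the library labelled SKBR3 TLE3 replicate 2. Estrogen response genes were near TLE3 for 16 of 17 in MDA-MB-453 (Fisher's exact test, adjusted p = 0.0108), 9 of 17 in SKBR3 (12 for replicate 1 alone) and 16 of 17 in T47D, led by TFF1, a secreted trefoil peptide, MREG and IGFBP4, a binding protein of insulin-like growth factors. Against matched random lists, 0 of the 39 lists and lines passed after Benjamini-Hochberg adjustment, with a lowest adjusted p = 0.902, and 1 did so unadjusted, the estrogen response genes in MDA-MB-453 (permutation p = 0.0160), and these numbers were again 0 and 1 without that library. The number of calls was 1 without MDA-MB-453 TLE3 replicate 2, where the adjusted p of the luminal genes in MDA-MB-453 was 0.0629 and that of the estrogen response genes 0.674, and 2 without SKBR3 TLE3 replicate 1, where that of the luminal genes in SKBR3 was 1. Without T47D TLE3 replicate 1 the luminal genes in T47D had an adjusted p of 0.823, and with sites taken from either replicate no list was called. The call of the luminal genes in SKBR3 also ended in the upper 50% of peaks by score (Fisher's exact test, adjusted p = 0.208). With equally long lists it ended too (Fisher's exact test, adjusted p = 0.481). In both, SKBR3 sites still need a peak of the library labelled TLE3 replicate 2, and 5 and 3 luminal genes had one. Without SKBR3 TLE3 replicate 1, SKBR3 sites come from that library alone. The calls in MDA-MB-453 and T47D ended without the densest regions (Fisher's exact test, adjusted p = 0.170 and 1). Genes in those regions were still counted. Luminal genes with a site fell from 20 to 18 and from 22 to 17, so this setting removes sites of the list genes themselves.

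The other 11 lists passed Fisher's exact test in no line. Basal identity genes had a TLE3 site within 50 kb for 12, 11 and 18 of 22 in MDA-MB-453, SKBR3 and T47D (17 for SKBR3 replicate 1 alone). The best ranked were ITGB4, an integrin of hemidesmosomes, SOX10 and TP63, a basal cell transcription factor, while KRT5, a basal keratin named in advance whatever its values, had none. BCL11A and the caveolin genes CAV1 and CAV2 had none in any line with all libraries, but 4, 2 and 2 for SKBR3 replicate 1 alone. Genes of epithelial-mesenchymal transition and TGF-beta signalling had one for 13, 7 and 13 of 18 (13 for SKBR3 replicate 1 alone), led by TGFB2, SMAD3 and CCN2, and CDH2, TGFBR1 and TWIST1 had none. WNT and TCF genes had one for 12, 5 and 11 of 15 (11), led by ZNRF3, TCF7L1 and CCND1, with none near SP5. NOTCH and HES genes had one for 11, 8 and 13 of 15 (11), led by HES1, BHLHE40 and HEY2. Androgen response genes had one for 13, 10 and 16 of 17 (13), with TSC22D3, a glucocorticoid-induced leucine zipper gene, and TMPRSS2, a serine protease gene, among the best ranked.

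ERBB pathway genes had a TLE3 site within 50 kb for 13, 6 and 15 of 16 (10 for SKBR3 replicate 1 alone), led by ERBB2 and its neighbour GRB7 and by EGFR, with none near the ligand gene NRG1. Corepressor genes had one for 13, 8 and 13 of 16 (9), led by TLE1, TLE3 and CTBP2, with none near HDAC3. RUNX, GRHL, AP-2, forkhead and GATA factor genes had one for 10, 7 and 14 of 15 (10), led by FOXA1, TFAP2A and GRHL3, with none near RUNX3. Cell cycle genes had one for 9, 7 and 14 of 18 (12), led by TOP2A, E2F1 and CCNB2, and BUB1 and CDK1 had none, while CCNB1 had 2 for SKBR3 replicate 1 alone and otherwise none. Housekeeping genes had one for 10, 5 and 11 of 15 (9), led by ACTB, RPLP0 and TUBB, with none near POLR2A and, for HPRT1, 1 for SKBR3 replicate 1 alone and otherwise none. Genes of other cell types had one for 9, 6 and 18 of 22 (15), led by the T cell genes CD3E and CD4 and the myeloid integrin gene ITGAM, with none near DCN and MYOD1 and, for NEUROD1, 2 for SKBR3 replicate 1 alone and otherwise none.

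FOXA1 sites lay within 50 kb of nearly all genes, so that the lists could not stand out. They were near 22 of 22 luminal genes in each line and near 21, 20 and 22 of 22 genes of other cell types in MDA-MB-453, SKBR3 and T47D, against 95.0%, 89.4% and 94.9% of all 19974 protein-coding genes. Of the 39 tests of FOXA1 sites, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment and 0 did so at an unadjusted p under 0.05, and the random lists matched on gene length gave 0 and 0. With equally long lists 3 passed.

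Some genes were named in advance whatever their values, and no test was made of them as a group. At least 1 TLE3 site lay within 50 kb of 53.4%, 33.9% and 73.4% of all protein-coding genes in MDA-MB-453, SKBR3 and T47D (55.6% for SKBR3 replicate 1 alone), so a site near any of them is not unusual. FOXA1 (chromosome 14, 37589552 to 37595249) had 7, 3 and 15 TLE3 sites within 50 kb in that order of lines (6 for SKBR3 replicate 1 alone), all at FOXA1 sites, and in T47D the best of them lay 46013 bp from a gene end (37640709 to 37641816). The TLE3 gene (chromosome 15, 70047790 to 70097917) had 5, 2 and 6 (4), including 1 inside the gene in T47D at 70093207 to 70094177. ESR1, the estrogen receptor alpha gene (chromosome 6, 151656672 to 152129619), had 1, 1 and 11 (3), of which 10 in T47D overlapped FOXA1, and the best in T47D lay inside the gene 1960 bp from an end. GATA3, a luminal transcription factor gene (chromosome 10, 8045333 to 8075198), had 3, 1 and 7 (3). ERBB2, a receptor tyrosine kinase gene (chromosome 17, 39688094 to 39728658), had 7, 10 and 11 (13), including 1 inside the gene in T47D at 39702565 to 39704059. KRT8, a luminal keratin gene (chromosome 12, 52897191 to 52949860), had 5, 5 and 10 (5), and TGFB2, a TGF-beta ligand gene (chromosome 1, 218345336 to 218444619), had 7, 2 and 5 (9). KRT5 (chromosome 12, 52514575 to 52520394) had 0 TLE3 sites in each line and 0, 4 and 1 FOXA1 sites. Numbers of sites per gene were not compared between lines because list lengths differ, and DNA copy number of the lines was not examined.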

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

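The tests of deeper calling and of a swap for the library labelled SKBR3 TLE3 replicate 2, and the test of list length, were chosen only after the results were seen. So was the choice to set values without that library beside the others, although leaving out each library in turn was planned.

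TLE3 peaks lay nearer gene ends than FOXA1 peaks in T47D, where the 2 libraries of TLE3 were both above the 2 of FOXA1 with a mean difference of 8.13 percentage points, and in SKBR3 (4.81, which rests on the library labelled SKBR3 TLE3 replicate 2, since for replicate 1 alone it was 0.442), but below them in MDA-MB-453 (−2.31). FOXA1 peaks with TLE3 were near gene ends more often than FOXA1 peaks without it in T47D (a difference of 6.23 percentage points) and SKBR3 (5.82) and less often in MDA-MB-453 (−3.91). These lines were set side by side because all libraries of a line moved the same way and those of another line the opposite way, and the difference between lines was not tested. In SKBR3 the FOXA1 values became −1.37 and −1.04 in the 2 libraries without the library labelled SKBR3 TLE3 replicate 2. The T47D TLE3 replicate 1 list held 4 mitochondrial peaks, which entered only the comparisons on all contigs.

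The library labelled SKBR3 TLE3 replicate 2 shared few of its 20000 highest scored peaks with any other list. Over all its peaks, the library overlapped another list for 4.18% (MDA-MB-453 TLE3 replicate 2) to 37.4% (MDA-MB-453 FOXA1 replicate 1). Deeper calling of the same target is argued against, since it held 33.9% of the peaks of replicate 1 where the longer TLE3 lists of the other lines held 97.0% and 96.8%. A swap with another of the peak lists is argued against as well (the 6 inputs were not examined), because 0 of the 10 lists whose replicate is not in doubt overlapped best with a list outside their group. A hypothesis is that the library may hold another target such as CTCF, which binds the clustered protocadherin genes: 86.5% of their alpha and gamma gene starts (32 of 37) had a peak within 1 kb. The bound set in advance also asked for at most 10% in the other lists, and T47D FOXA1 replicate 1 reached 37.8%, so this stays open beside a sample from outside the series, and no biological explanation was tested.

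TLE3 peaks without FOXA1 lay nearer gene ends in the 5 other TLE3 libraries. FOXA1 peaks missed by joining replicates are argued against: with the peaks of all 6 FOXA1 lists as partners the mean difference was −16.9 percentage points, from −26.3 to −8.29, the last on 159 peaks without FOXA1. Weak TLE3 calls are argued against by the upper 50% of peaks by score, where it was −28.3, from −38.2 to −19.5, although MDA-MB-453 TLE3 replicate 2 had 9 such peaks without FOXA1 and replicate 1 had 67. That TLE3 may reach gene ends through partners other than FOXA1 is a hypothesis that these lists do not test, and open promoter chromatin that precipitates without a partner also stays open.

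The overlap of TLE3 with FOXA1 far exceeded random placement. Chromatin open in any of the lines, as the whole cause, would put TLE3 at sites with FOXA1 in another line alike with or without FOXA1 in its own, but TLE3 was at least 5.95 times as frequent with it in each of the 5 libraries, the lowest ratio being in T47D TLE3 replicate 2. The length of the FOXA1 lists as the source of the own-line excess is argued against by equally long lists of 21149 peaks. There own-line overlap still exceeded other-line overlap by at least 13.7 percentage points in each of the 5. The overlap of sites itself fell to 71.1% in MDA-MB-453, 46.0% in SKBR3 and 58.5% in T47D with these lists, so its size depends on list length. Binding of TLE3 through FOXA1 may account for the overlap as a hypothesis, and chromatin open in the own line alone, or signal that any immunoprecipitation gives at such regions, was not tested.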

How the results depend on the processing

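The settings with a score of 10 or more, random shifts by 10 to 100 kb, the gene body, and lists matched on gene length were chosen only after the data were seen. Over 17 results, 259 of 288 values under alternatives kept their direction and side of the threshold or stayed within the limits set for counts, and none reversed. This tally is lenient, since an overlap counted as kept wherever it passed against random placement, however far its value moved. For sign-flip tests with a main p of 0.0625, leaving out a TLE3 library could not change the side, since 5 libraries cannot go below 0.0625. The overlap of TLE3 sites with FOXA1 stayed above random placement under each of its 14 alternatives per line, from 71.1% to 99.8% in MDA-MB-453, 21.7% to 93.5% in SKBR3 and 58.5% to 92.9% in T47D. The log2 difference of peak numbers ranged from −2.21 to −1.49, the difference between own and other lines from 14.5 to 22.3 points and that of gene ends between factors from 1.29 to 5.0.

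The difference of peaks near gene ends with and without FOXA1 passed the test at −18.2 with an overlap of 50% of the shorter interval. It passed at −11.2 with centres within 250 bp (exact permutation p = 0.0313 in both). This p needs all 6 libraries to share a sign. The library labelled SKBR3 TLE3 replicate 2, at 2.11 in the main run, was thus negative in both. Why that library changed sign was not tested. The strength of TLE3 peaks passed at 0.705 in the upper 50% by score and 0.749 with either replicate, cause not tested. A pass needs all 6 libraries above 0.5, not a larger mean. It was 0.592 with centres within 250 bp and 0.673 among peaks of similar width, and passed in neither. For FOXA1 strength, leaving out 1 library gave 0.780 to 0.877, and the calls it ended were those with 5 FOXA1 libraries, which cannot reach the threshold. With equally long lists FOXA1 strength fell to 0.687. TLE3 sites in all 3 lines numbered 247 in the upper 50%, 863 at a score of 10 or more, 155 with equally long lists, 1494 with centres and 12654 with either replicate, and 2263 to 6365 with 1 library left out, the highest without the library labelled SKBR3 TLE3 replicate 2. FOXA1 sites in all 3 lines numbered 22559, 6636 and 66852 in the upper 50%, with equally long lists and with either replicate; fewer or more peaks enter by construction. TLE3 list calls numbered 0 with either replicate and 2 without the densest bins, whose genes were still counted. They numbered 8 at 10 kb, 2 at 100 kb, 17 with the nearest gene alone and 1 to 4 with 1 library left out. The call of the estrogen response genes in MDA-MB-453 ended in the upper 50% by score (Fisher's exact test, adjusted p = 0.267), at a score of 10 or more (0.0651), with centres (0.0603), at 10 kb (0.0769) and at 100 kb (0.141), and that of the luminal genes in T47D at 100 kb (0.752). FOXA1 list calls numbered 3 with equally long lists, 2 at 10 kb and 5 with the nearest gene alone. At 50 kb nearly all genes have a FOXA1 site, so shorter distances leave more room, and the cause was not otherwise tested.

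Of 1152 values for 64 named genes 932 kept the number of lines with a TLE3 site, and of 439 for 45 named sites 363 kept their percentile within 1 SD of the replicates where an overlapping site remained. Libraries share replicate numbers, and pairing them by number left the log2 difference at −1.85 (exact permutation p = 0.0313) and that of gene ends at 3.54 (p = 0.219), with TLE3 overlap at 98.5%, 59.3% and 81.7% and FOXA1 overlap at 18.1%, 19.1% and 23.9%; no call changed. The replicate differences of same-numbered libraries correlated across sites at 0.0888, 0.0549 and −0.0737, which gave no sign that same-numbered libraries are paired. The forkhead motif alternatives were not run, for lack of a genome sequence here. Depth is unknown, so whether list length reflects binding or sequencing cannot be decided from these lists.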

Other observations

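The comparisons at 10 kb and with lists matched on FOXA1 sites were fixed before the data were seen, and the lists matched on gene length and the values without the library labelled SKBR3 TLE3 replicate 2 were chosen only after.

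Closer to genes, other groups stood beside the luminal ones. Within 10 kb of a gene end, 8 of 39 lists and lines passed Fisher's exact test for TLE3 (7 without the library labelled SKBR3 TLE3 replicate 2). Luminal genes had a TLE3 site for 16 of 22 in MDA-MB-453 (Fisher's exact test, adjusted p = 7.99e-06), 10 of 22 in SKBR3 (0.00536, and 16 of 22 for replicate 1 alone, 6.57e-05) and 21 of 22 in T47D (7.75e-06). FOXA1 sites also lay within 10 kb of 22 of 22 luminal genes in each line (Fisher's exact test, adjusted p = 0.0551, 0.00132 and 0.0382 in the same order), the list of both FOXA1 calls at this distance. Against lists matched on gene length the luminal genes passed for FOXA1 in SKBR3 (one-sided permutation, adjusted p = 0.00780) and not in MDA-MB-453 (0.0811) or T47D (0.0520). Estrogen response genes had a TLE3 site for 16 of 17 in T47D (Fisher's exact test, adjusted p = 0.000174), and ERBB pathway genes for 13 of 16 in T47D (0.0190). Corepressor genes, the family of TLE3 among them, had one for 9 of 16 in MDA-MB-453 (0.0201). NOTCH and HES genes, which encode targets and partners of Groucho repression, had one for 8 of 15 in MDA-MB-453 (0.0393) and 7 of 15 in SKBR3 (0.0223). The last call is the one that ended without the library labelled SKBR3 TLE3 replicate 2, at 8 of 15 (Fisher's exact test, adjusted p = 0.0821). Against lists matched on FOXA1 sites, 1 of the 39 passed after adjustment, the NOTCH and HES genes in SKBR3 (one-sided permutation, adjusted p = 0.0390), and 7 had an unadjusted p under 0.05; without the library labelled SKBR3 TLE3 replicate 2 these numbers were 0 and 6.

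Whether luminal genes attract TLE3 beyond their number of FOXA1 sites stays open. At 50 kb the lowest one-sided permutation p against lists matched on FOXA1 sites was 0.229 over the 3 lines, so the number of FOXA1 sites may account for the closeness of TLE3 to these genes, but T47D had 22 of 22 against a matched mean of 21.6, which left almost no room for an excess. At 10 kb, luminal genes with a TLE3 site numbered 16 against a mean of 12 in lists matched on FOXA1 sites within that distance in MDA-MB-453 (one-sided permutation p = 0.0469, adjusted 0.215, and 0.0545 in a further set of random lists). In SKBR3 they numbered 10 against 9.42 (one-sided permutation p = 0.485, and 16 against 14.1 with p = 0.232 for replicate 1 alone) and in T47D 21 against 18.5 (p = 0.0902).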
